A study of Mus musculus with 8 samples.

How the data were processed

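RNA was sequenced from macrophages enriched with F4/80 magnetic beads from the inguinal fat pads of wild-type female mice. Per the labels' protocols, mice received 62.5 mg of Aldara cream, which holds 5% imiquimod, an agonist of Toll-like receptor 7, on shaved dorsal skin on 3 consecutive days. Control mice received an equivalent volume of a control cream, and tissue was taken 24 h after the last application. The 2 groups, called Aldara and Vehicle here, hold 4 libraries each. Each library pooled cells from 6 fat pads, about 30000 cells, and preparations with more than 90% of cells positive for F4/80 and CD64 by flow cytometry went on to RNA extraction. The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these pools. Amplification used a SMARTer ultra-low-input kit with poly-A enrichment, and this kit does not mark the strand. Reads of overlapping or antisense genes can therefore not be told apart.

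The deposited table holds whole-number counts of reads per gene, not normalised, for all 8 libraries. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 were used with the mm10 build, with no DESeq2 version given. The counting options are not given in the sources used here. The table has 56748 rows keyed by Ensembl gene identifier, of which 25044 hold 0 in every library. Identifiers were looked up in GENCODE M21, which gave a symbol for 52073 of them (91.8%). The 4675 unmatched identifiers carried between 0.71% and 1.29% of the counts of a library and were kept under their identifiers. Some identifiers are more recent than that annotation, so it was used for names and gene types only and no coordinates are printed. The row of Armh3 carries a hand-written note naming Ccr2, whereas the identifier of Ccr2 has a row of its own, and the latter was used for Ccr2. Genes that share sequence with pseudogenes or overlap another gene can be undercounted, so a low level of such a gene does not show that it was absent.

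Total counts per library ranged from 19537607 to 34471508. At these depths 1 count is worth less than 0.1 CPM, and intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 16780, libraries were scaled with TMM factors (0.957 to 1.035), and Aldara was compared with Vehicle by the robust quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. All adjusted p-values for genes come from this test unless another is named. Levels are TMM-scaled CPM (counts relative to the effective library size) computed from the deposited counts and given as mean ± SD with n = 4 libraries per group. Log2 fold changes are Aldara minus Vehicle, with the standard error (SE) derived from the F statistic. Gene lists were tested on log2 CPM (prior count of 2) with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 35 lists that had at least 5 tested members. Camera with an estimated correlation and fry were run beside it.

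The lists, the tests and the alternatives were fixed before the data were examined. They comprise 24 lists of macrophage and cellular programs and 15 lists of markers of other cell types that a fat pad preparation could hold. Some genes stand in several lists, such as Mgl2, Lipa, Cd36 and Lcn2. Genes are named by a fixed rule. The rule takes the 8 largest rises and the 8 largest falls among genes past the threshold with at least 5 CPM in the higher group and groups that do not overlap, then the 3 smallest p-values in each direction beyond these. Predicted gene models were left out of both parts, which removed 1 gene among the falls. The rule also takes up to 4 members of each list by smallest p, and always Adgre1, Fcgr1, Ptprc, Cd68, Itgam and Tlr7. Of the genes so taken, 2 are not reported here. Krt8, Krt18, Epcam, Csf1r, C1qa, Lyve1, Timd4, Pgr, Gpx3, Esr1, Foxa1, Prlr, Cd79a, S100a8, S100a9 and the genes named only among the closing observations were chosen after their values were seen.

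The procedure was tested on simulated counts for the comparison of Aldara with Vehicle, drawn for the 16780 genes from the means and library sizes of these libraries with 200 genes changed. It recovered 57% of the genes changed by 1 on the log2 scale and 92% of those changed by 2, with 0 sign errors. Of its calls, 4.49% were unchanged genes. Genes were drawn independently of each other, whereas members of a list vary together between the real libraries. These rates therefore need not hold for the real calls. Libraries were compared for duplicates, and the closest pair of a group still differed by a chi-square of 20.6 per degree of freedom, far beyond sampling noise. The replicate numbers in the labels are shared between the groups. Deviations from the group means correlated across genes at 0.228, 0.108, 0.167 and 0.218 for libraries of equal number, and each library correlated best with its own number. The numbers were therefore treated as possibly pairing the libraries. The pairing comes from this check and not from the labels, and the labels name no shared batch or day. The check used the same counts as the tests and its correlations were low, so the pairing stays uncertain. Blocked p-values, which are often smaller, hold only if the pairing is real. The fit without the block stayed the main one, as fixed beforehand, and a blocked value is given where it changes a call or moves a count by more than 1.5 times.

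Alternatives were median-of-ratios and upper-quartile scaling, no low-count filter beyond dropping genes at 0 in all libraries, a filter of at least 1 CPM in 4 libraries, protein-coding genes alone, the replicate number as a block, and leaving out each library in turn. DESeq2 1.42.0 (Wald test), limma voom with sample quality weights, a fit with robust=FALSE and a minimum absolute log2 fold change of 1 were also run.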

Results

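Libraries from F4/80-enriched fat pad cells of mice treated with imiquimod cream (Aldara, 4 libraries) were compared with libraries from mice given control cream (Vehicle, 4 libraries). The comparison asks how the cells of the inguinal fat pad collected as macrophages differ after a cream with a Toll-like receptor 7 agonist on the skin. It cannot separate imiquimod from other constituents of Aldara that the control cream may lack. Total counts per library ranged from 21874780 to 34471508 in Vehicle and from 19537607 to 24340674 in Aldara. This difference lay within the spread between libraries (n = 4 each, two-sided exact permutation of unpaired libraries, p = 0.286). On log2 CPM, Pearson correlations across genes were 0.976 to 0.988 within Vehicle, 0.977 to 0.987 within Aldara and 0.952 to 0.979 between the groups. The first principal component held 47.8% of the variance and separated the 4 Vehicle libraries (−51.2 to −23.9) from the 4 Aldara libraries (14.7 to 48.6).

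Of the genes behind the purity gate, Adgre1 (ENSMUSG00000004730), which encodes F4/80, rose from 82.5 ± 20.4 CPM in Vehicle to 967 ± 476 CPM in Aldara. Its log2 fold change was 3.55 (SE 0.4, adjusted p = 0.0021). Fcgr1, which encodes CD64, measured 19.7 ± 1.85 CPM in Vehicle and 26.5 ± 12.3 CPM in Aldara and did not pass the test (adjusted p = 0.436). Itgam, the integrin chain CD11b, rose from 18 ± 4.57 to 143 ± 71.1 CPM (log2 fold change 2.99, SE 0.39, adjusted p = 0.0033). Ptprc, the pan-leukocyte antigen CD45, rose from 41.6 ± 6.5 to 151 ± 62.8 CPM (adjusted p = 0.0064). Cd68, a lysosomal glycoprotein of macrophages, measured 72.6 ± 17.3 and 133 ± 47.3 CPM (adjusted p = 0.0666, and 0.00233 with the replicate block). Tlr7, the receptor of imiquimod, measured 19 ± 6.42 and 38.9 ± 18.5 CPM (adjusted p = 0.118, and 0.00209 with the replicate block). Csf1r, the receptor of the macrophage growth factor, measured 274 ± 70.4 and 543 ± 211 CPM (adjusted p = 0.0648, and 0.00114 with the replicate block). Without Aldara replicate 1, Cd68 (adjusted p = 0.0101), Tlr7 (0.0332) and Csf1r (0.0169) passed the threshold.

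Transcripts of epithelial cells were abundant in all 8 libraries. Krt8 and Krt18, keratins of simple epithelia, measured 4140 ± 935 and 2760 ± 459 CPM in Vehicle and 4170 ± 586 and 2500 ± 246 CPM in Aldara. Epcam, an epithelial adhesion molecule, measured 1480 ± 45.2 and 1390 ± 100 CPM. None of these 3 genes, Krt8, Krt18 and Epcam, passed the test (adjusted p = 0.978, 0.58 and 0.636). The median member of the mammary and skin epithelium list lay between 465 and 700 CPM in every library, whereas the median of 23 macrophage genes, chosen after the data were seen, lay between 53.4 and 280 CPM. Single macrophage genes reached the level of Epcam in some Aldara libraries, with Adgre1 at 1413 CPM against 1244 CPM for Epcam in Aldara replicate 3. Of the 12 tested members of the epithelial list, Lcn2, an iron-binding lipocalin, rose (log2 fold change 0.81, SE 0.11, adjusted p = 0.00268) and Krt15 fell (−1.12, SE 0.27, adjusted p = 0.0286), with a list median of 0.02 (1 and 1 adjusted over the list alone, 2 and 1 with the replicate block). The list as a whole was not called (camera adjusted p = 0.769). The call on Krt15 was lost without Vehicle replicate 1 or without Aldara replicate 2, 3 or 4 (highest adjusted p = 0.0889).

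**Figure D1:**
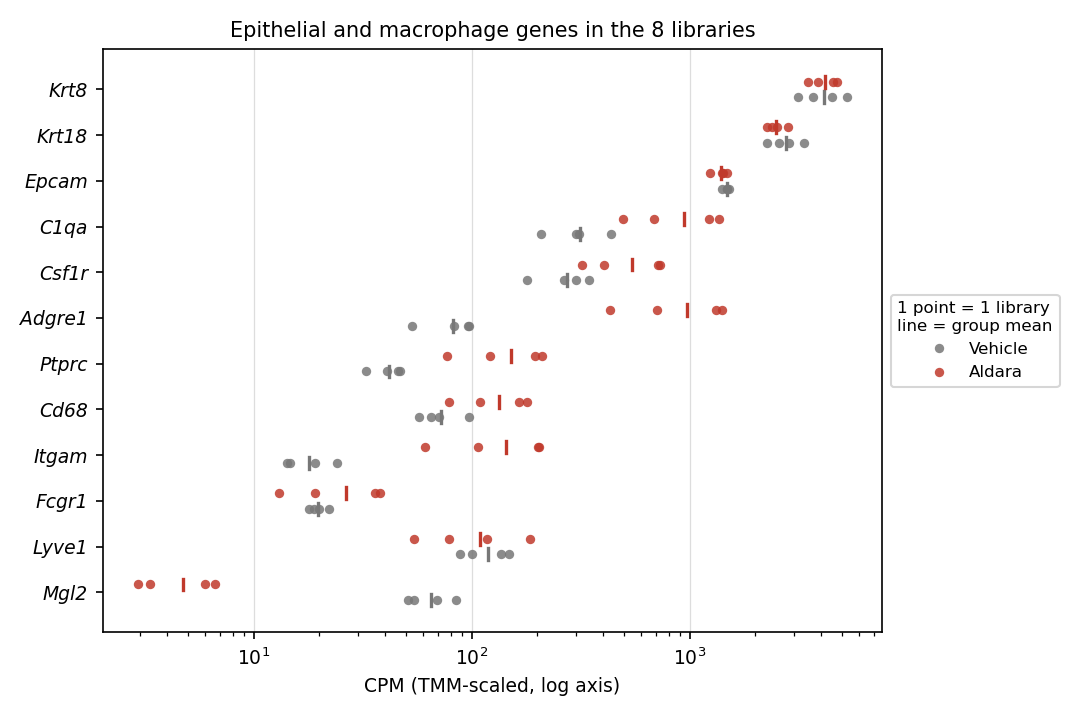
TMM-scaled CPM (log axis) of 3 epithelial and 9 macrophage genes, with 1 point per library and a line at the group mean. Krt8, Krt18 and Epcam lie above 1000 CPM in every library, Adgre1 is higher in the 4 Aldara libraries (mean 967 CPM) than in the 4 Vehicle libraries (82.5 CPM), and Mgl2 is lower (4.73 against 65 CPM).

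Across the transcriptome, 1171 genes rose and 647 fell with Aldara, which together are 10.8% of the 16780 genes tested. The largest rises were those of Fcrl5 (ENSMUSG00000048031), an Fc receptor-like protein, from 0.0435 ± 0.0606 to 13.3 ± 7.23 CPM, and of Cd300e, an activating receptor of myeloid cells, from 0.119 ± 0.144 to 17.1 ± 8.42 CPM. Marco, a scavenger receptor, rose from 0.498 ± 0.417 to 71.1 ± 43.5 CPM (log2 fold change 7.02, SE 0.67, adjusted p = 0.00121). Saa3, an acute-phase protein, rose by 6.92 on the log2 scale (SE 0.59) and Fpr1, a receptor for formylated peptides, by 6.3 (SE 0.52). Slc13a3, a dicarboxylate transporter, went from 8.77 ± 1.16 to 565 ± 331 CPM. Sirpb1a and Itgal, an integrin chain of leukocytes, rose by 5.74 (SE 0.52) and 5.43 (SE 0.47), where reads of Sirpb1a may be shared with close paralogs. For each of these 8 genes the adjusted p lay at or below 0.00121 and the 4 Aldara libraries were above the 4 Vehicle libraries.

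The largest fall was that of Tmprss11a, a membrane serine protease, with 519 counts over the Vehicle libraries and 1 over the Aldara libraries, a ratio of 433 (95% exact interval 77.4 to 17100, counting error only). Aoc1, a diamine oxidase, went from 69.7 ± 102 to 0.247 ± 0.253 CPM, and Sbp from 7.27 ± 5.81 to 0.205 ± 0.0396 CPM. Ptpn5, a tyrosine phosphatase, went from 82.3 ± 80 to 3.35 ± 2.68 CPM, and Greb1, an oestrogen-regulated gene, from 17.4 ± 22.1 to 0.973 ± 0.129 CPM. Mgl2 (ENSMUSG00000040950), a C-type lectin of macrophages and dendritic cells, fell from 65 ± 15.5 to 4.73 ± 1.86 CPM (log2 fold change −3.79, SE 0.29, adjusted p = 0.000794). Chst8, a sulfotransferase, and Fam83e fell by 3.61 (SE 0.91) and 3.54 (SE 0.89) on the log2 scale. The Vehicle libraries spread widely for several of these genes. The calls on Aoc1, Ptpn5, Greb1, Chst8 and Fam83e were lost without any 1 of the 4 Aldara libraries, with highest adjusted p-values of 0.102, 0.0989, 0.106, 0.12 and 0.142. The calls on Ptpn5, Chst8 and Fam83e were also lost without Vehicle replicate 2, that on Fam83e without Vehicle replicate 1, and that on Tmprss11a without Aldara replicate 1 (adjusted p = 0.0592).

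**Figure D2:**
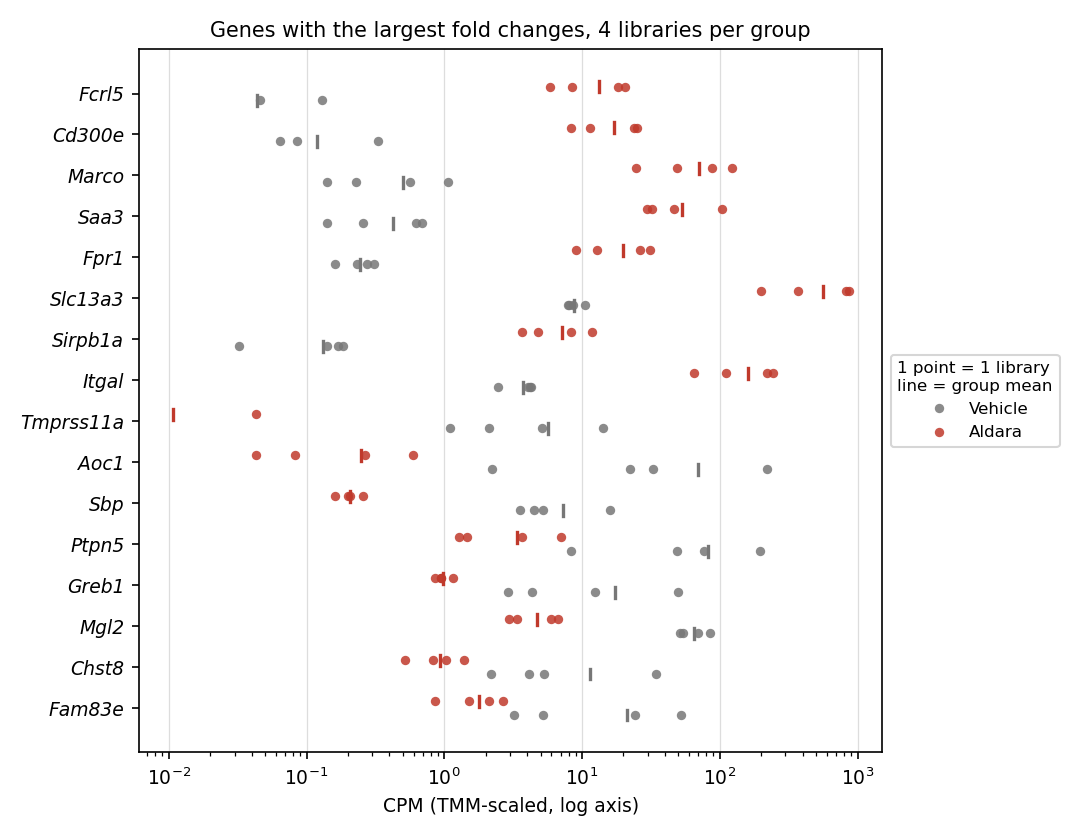
TMM-scaled CPM (log axis) of the 8 genes with the largest rises, then the 8 with the largest falls, with 1 point per library and a line at the group mean. Libraries with no count of a gene are not drawn, and for each gene the groups do not overlap, as for Slc13a3 (means of 8.77 CPM in Vehicle and 565 CPM in Aldara).

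Beyond these, small p-values among rising genes belonged to Clca3a2, a chloride channel accessory protein, at 239 ± 30.7 and 1040 ± 186 CPM, and to Trdv4, a variable segment of the T cell receptor delta locus. Their log2 fold changes were 2.11 (SE 0.15) and 1.51 (SE 0.14). Clca3a2 has close paralogs and Trdv4 lies among overlapping receptor segments, so the source of their reads is uncertain. Among falling genes the smallest p-values belonged to Bdnf, a neurotrophin, at 27.4 ± 4.69 and 6.37 ± 1.03 CPM, to Zbtb8a, and to Trem2, a lipid-sensing receptor of macrophages. Their log2 fold changes were −2.1 (SE 0.16), −1.5 (SE 0.13) and −2.88 (SE 0.25).

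The groups did not overlap for 2981 of the 16780 genes tested (17.8%), where chance gives 2.86%. These included 1069 of the rising and 601 of the falling genes. The change was at least 2-fold for 511 rising and 227 falling genes. The balance of directions depended on the scaling, with 1171 rising and 647 falling genes under TMM (64.4% rising) and 979 and 990 under upper-quartile factors (49.7% rising). The number of falling genes was 1030 with the replicate block and 1154 with DESeq2. Without Vehicle replicate 1 or 2 the rising and falling genes numbered 703 and 415 or 699 and 412, without Aldara replicate 3 they numbered 658 and 323, falling genes numbered 353 without Aldara replicate 2, and rising genes 629 without Aldara replicate 4.

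Several genes of endosomal nucleic acid sensing were higher in Aldara. In the list of the Toll-like receptor 7 pathway, 9 of 15 genes rose and 0 fell (11 adjusted over the list alone), with a median log2 fold change of 1.02. Unc93b1, the chaperone of endosomal Toll-like receptors, rose from 171 ± 18.5 to 556 ± 210 CPM. Slc15a3, a lysosomal peptide transporter, rose by 2.43 (SE 0.38), Tlr9, a sensor of CpG DNA, by 2.09 (SE 0.35) and Irak3, an inhibitory kinase of this pathway, by 1.42 (SE 0.24), all on the log2 scale. The camera adjusted p of the list was 1.87e-06, and the call was lost with an estimated correlation (adjusted p = 0.46). The geometric mean of the 23 macrophage genes used above, called the macrophage reference here, lay between 50.2 and 95.5 CPM in the Vehicle libraries and between 124 and 321 CPM in the Aldara libraries. That reference was thus 1.62 higher on the log2 scale in Aldara, more than the median of this or of any other list.

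In both lists of interferon-related genes more members rose than fell. In the interferon-stimulated list 8 of 32 genes rose and 1 fell (9 and 3 adjusted over the list alone). Rtp4, a chaperone of receptors, rose by 0.69 (SE 0.12), Ddx58, the RNA sensor RIG-I, by 0.47 (SE 0.08) and Parp14 by 0.57 (SE 0.12), whereas Ifit2, a translation inhibitor, fell from 20.3 ± 2.13 to 12.9 ± 0.995 CPM. The list median was 0.29 and its camera adjusted p 0.0288 (adjusted p = 0.794 with an estimated correlation). That call was lost without Vehicle replicate 1 or without Aldara replicate 3 or 4 (highest adjusted p = 0.191). In the list of interferon-gamma-inducible GTPases and immunoproteasome genes 11 of 23 rose and 2 fell (14 and 3 adjusted over the list alone). Cd274, the checkpoint ligand PD-L1, rose from 7.13 ± 0.535 to 24.8 ± 7.66 CPM, Igtp by 0.99 (SE 0.14), and the guanylate-binding proteins Gbp3 and Gbp5 by 0.9 (SE 0.14) and 0.87 (SE 0.13). The median was 0.39, beside 1.62 for the macrophage reference, and the camera adjusted p 5.75e-05 (adjusted p = 0.46 with an estimated correlation).

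Complement genes showed the highest list median, 1.41, which lay under the 1.62 of the macrophage reference, with 10 of 15 members risen and 1 fallen (12 and 1 adjusted over the list alone). Cfp, which stabilises the alternative convertase, rose from 130 ± 26.5 to 606 ± 272 CPM, and C3ar1, a receptor of the C3a fragment, from 47.5 ± 12.1 to 200 ± 98.1 CPM. C4b rose by 1.41 (SE 0.23), where near-identical copies of this gene may share reads, and Itgam by 2.99 as given above. C1qa, a chain of the complement component C1q, rose from 314 ± 93.6 to 943 ± 420 CPM (adjusted p = 0.0201), a call lost without Vehicle replicate 1, 2 or 4 or Aldara replicate 3 or 4 (highest adjusted p = 0.073). Relative to the macrophage reference, which holds C1qa, it measured −0.1 (SE 0.44). For the complement list the camera adjusted p was 1.42e-06 (adjusted p = 0.46 with an estimated correlation).

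Lysosomal genes rose in part. Of 26 members 12 rose and 0 fell (20 adjusted over the list alone), with a median of 0.58 beside 1.62 for the macrophage reference. Psap, the precursor of the saposins, rose from 1360 ± 98.7 to 2410 ± 506 CPM, Lipa, the lysosomal acid lipase, from 83.8 ± 12.9 to 164 ± 36.9 CPM, and Ctsh, a cathepsin, by 0.77 (SE 0.16). For the lysosome list the camera adjusted p was 4.84e-08 (adjusted p = 0.501 with an estimated correlation). In the list of cholesterol efflux and LXR targets 6 of 13 genes rose and 0 fell (7 adjusted over the list alone). Abca1, a cholesterol exporter, rose from 128 ± 30.7 to 378 ± 109 CPM, Pltp, a phospholipid transfer protein, from 197 ± 59.5 to 899 ± 386 CPM, and Smpdl3a and Mylip by 0.91 (SE 0.15) and 0.83 (SE 0.15). The median was 0.83, also under that of the macrophage reference, and the camera adjusted p 0.000843 (adjusted p = 0.501 with an estimated correlation). None of the 21 tested genes of cholesterol synthesis and uptake passed edgeR, DESeq2 or voom, with 1 at an unadjusted p under 0.05. Its gene of smallest p, Fdft1, measured 65.8 ± 8.52 and 54.3 ± 8.28 CPM, and the list was not called (camera adjusted p = 0.381).

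In the efferocytosis list 5 of 20 genes rose and 0 fell (9 and 1 adjusted over the list alone, 8 and 0 with the replicate block). Besides Marco, the scavenger receptor Cd36 rose by 0.83 (SE 0.15), Pros1, a ligand of TAM receptors, by 0.65 (SE 0.13) and the endocytic receptor Lrp1 by 0.93 (SE 0.18). The median was 0.34 and the camera adjusted p 0.00248 (adjusted p = 0.46 with an estimated correlation). In the iron and haem list 5 of 15 genes rose and 0 fell (7 adjusted over the list alone). Slc11a1, a phagosomal metal transporter, rose from 34.4 ± 5.81 to 168 ± 79.4 CPM and Cp, a ferroxidase, from 265 ± 26.9 to 487 ± 43.7 CPM. Blvrb, a biliverdin reductase, rose by 0.78 (SE 0.13) and Ftl1, the ferritin light chain, by 1.29 (SE 0.23), where pseudogenes of Ftl1 may take some of its reads. The list median was 0.32 and the camera adjusted p 0.000445 (adjusted p = 0.501 with an estimated correlation). The macrophage reference lay 1.62 higher beside both lists.

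Of 21 markers of tissue-resident macrophages 6 rose and 1 fell (13 and 1 adjusted over the list alone, 14 and 1 with the replicate block), with a median of 0.9 beside 1.62 for the macrophage reference. Fcrls, an Fc receptor-like scavenger receptor, rose from 72.1 ± 15.3 to 462 ± 254 CPM, the lectin Cd209f from 104 ± 25.1 to 336 ± 150 CPM and the complement receptor Vsig4 from 1.04 ± 0.741 to 4.16 ± 0.848 CPM, whereas Mgl2 fell. Lyve1, a hyaluronan receptor, measured 119 ± 28.8 and 109 ± 56.9 CPM (adjusted p = 0.865), and Timd4, a phosphatidylserine receptor, 15.1 ± 2.43 and 13.7 ± 5.92 CPM (adjusted p = 0.815). For the resident list the camera adjusted p was 0.000596 (adjusted p = 0.68 with an estimated correlation).

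Lists of other macrophage states held members that moved in opposite directions and were not called. Of 15 alternative-activation genes 2 rose and 4 fell (3 and 7 both adjusted over the list alone and with the replicate block). The receptor Cd200r1 rose by 2.12 (SE 0.33) and the chitinase-like Chil3 by 2.88 (SE 0.57), where a near-identical copy of Chil3 may share reads. Mgl2 and the signalling inhibitor Socs2 (−0.7, SE 0.12) fell, and the list had a camera adjusted p of 0.155. Of 21 lipid-associated macrophage genes 5 rose and 3 fell (9 and 3 adjusted over the list alone, 8 and 3 with the replicate block). Lipa and Cd36 rose, whereas Trem2 and the tetraspanin Cd9 (693 ± 72.3 to 422 ± 42.6 CPM) fell (list adjusted p = 0.247). Of 14 monocyte genes 2 rose and 3 fell (2 and 4 adjusted over the list alone). Cd300e and the lectin Clec4a3 (2.81, SE 0.37) rose and Plac8 fell from 51.4 ± 12.3 to 24.8 ± 2.77 CPM. The median of this list was −0.26 and its mean 0.3, camera placed it downwards, and it was not called (adjusted p = 0.567).

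Inflammatory mediators were mixed as well. Among 22 cytokines and NF-kB targets 3 rose and 3 fell (5 and 3 adjusted over the list alone, 5 and 4 with the replicate block). Saa3 rose, Relb, a subunit of NF-kB, rose from 67.8 ± 7.55 to 105 ± 6.06 CPM and Cd14, the endotoxin co-receptor, from 375 ± 15.1 to 604 ± 108 CPM. Tnfsf9, the ligand 4-1BBL, fell from 20.6 ± 4.53 to 7.9 ± 0.888 CPM (list adjusted p = 0.769). Among 19 chemokines 3 rose and 1 fell (4 and 1 adjusted over the list alone, 5 and 4 with the replicate block). Cxcl13, which attracts B cells, rose from 0.648 ± 0.453 to 17.4 ± 9.75 CPM, and the monocyte attractant Ccl12 fell from 4.59 ± 1.21 to 1.28 ± 0.818 CPM, a call lost without Aldara replicate 4 (adjusted p = 0.0543). The chemokine list was not called (adjusted p = 0.756). Of 14 genes of MHC class II presentation 3 rose and 0 fell (4 and 0 adjusted over the list alone, 4 and 1 with the replicate block), among them Ctss, the protease of the invariant chain (94.9 ± 31.9 to 257 ± 105 CPM), and Cd86, a costimulatory ligand (20.9 ± 7.42 to 68.2 ± 32.2 CPM). Both calls were lost without Vehicle replicate 1, 2 or 4 or Aldara replicate 3 or 4 (highest adjusted p = 0.0873 for Ctss and 0.0892 for Cd86). The list median was −0.03 and its mean 0.21, and camera placed it upwards without a call (adjusted p = 0.657).

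Of 21 genes of matrix remodelling 3 rose and 4 fell (5 and 5 both adjusted over the list alone and with the replicate block). The metalloproteinase Mmp19 rose by 1.82 (SE 0.32), whereas Mmp12, the macrophage elastase, and Sparc, a matrix protein, fell by 2.93 (SE 0.6) and 0.76 (SE 0.15) on the log2 scale (list adjusted p = 0.155). Of 18 growth and angiogenic factors 5 rose and 2 fell (5 and 3 adjusted over the list alone). Pdgfb rose from 25.8 ± 1.22 to 46.6 ± 12.3 CPM, and Areg, an epidermal growth factor receptor ligand, fell from 836 ± 206 to 167 ± 96.8 CPM (list adjusted p = 0.769).

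Genes of proliferation and respiration were lower as lists, with few members past the threshold. Of 32 cell cycle genes 0 rose and 2 fell, against 9 fallen with the replicate block and 1 adjusted over the list alone. Mcm2, of the replicative helicase, fell from 41.2 ± 4.17 to 27.2 ± 0.625 CPM and Mcm7 from 37.3 ± 8.92 to 25.5 ± 2.05 CPM. Birc5 and Nusap1, of the mitotic spindle, measured 4.01 ± 2.73 and 4.93 ± 3.21 CPM in Vehicle and 1.49 ± 0.475 and 1.99 ± 0.294 CPM in Aldara (adjusted p = 0.0811 and 0.0899, and 0.0321 and 0.048 with the replicate block). Without Vehicle replicate 2 both passed the threshold (adjusted p = 0.0473 and 0.0435), as did Nusap1 without Vehicle replicate 1 (0.0467). The higher Vehicle means rest on replicates 3 and 4 (7.4 and 5 CPM for Birc5, 8 and 7.4 CPM for Nusap1). Vehicle replicates 1 and 2 (1.9 and 1.7 CPM, 2.2 and 2.1 CPM) lay within the range of the Aldara libraries. The list median was −0.81 and the camera adjusted p 2.4e-05 (adjusted p = 0.68 with an estimated correlation). Of 35 nuclear-encoded genes of oxidative phosphorylation 0 rose and 4 fell, 13 with the replicate block and 9 adjusted over the list alone. Atp5b, of the ATP synthase, fell from 954 ± 59.8 to 744 ± 29.3 CPM. Uqcrfs1, Cyc1 and Uqcrc2, of complex III, fell by 0.4 (SE 0.09), 0.33 (SE 0.09) and 0.24 (SE 0.07). The median was −0.27 and the camera adjusted p 1.8e-07 (adjusted p = 0.501 with an estimated correlation). The call on Mcm2 held without any 1 library (highest adjusted p = 0.0137). The other gene calls in these lists did not, since those on Atp5b and Uqcrc2 were lost without any 1 of the 8 libraries, that on Mcm7 without any library but Vehicle replicate 1, that on Cyc1 without Vehicle replicate 1 or 3 or Aldara replicate 2, 3 or 4, and that on Uqcrfs1 without Aldara replicate 3, with highest adjusted p-values of 0.0902, 0.114, 0.0907, 0.0882 and 0.0526. The share of counts on mitochondrial genes was also lower, at 1.05 ± 0.105% in Aldara against 1.63 ± 0.377% in Vehicle. With n = 4 each, the two-sided exact permutation p over unpaired libraries was 0.0286, the smallest possible without the pairing. The pairing by replicate number was not used in this test.

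The remaining program lists were not called. Of 17 glycolysis genes 2 rose and 1 fell (2 and 5 adjusted over the list alone, 2 and 2 with the replicate block), led by the rise of the hexokinase Hk3 (1.99, SE 0.31), and the list's adjusted p of 0.0672 ranged from 0.00379 to 0.168 when single libraries were left out, with calls, downwards, without Vehicle replicate 3 and without Aldara replicate 3. It was also called with no low-count filter (adjusted p = 0.0339). Of 7 genes of catecholamine handling 2 rose and 0 fell (2 and 2 adjusted over the list alone, 2 and 1 with the replicate block). The median was −0.04 and the mean 0.01, and camera placed the list downwards without a call (adjusted p = 0.769). Of 16 glucocorticoid-induced genes 1, Lcn2, rose and 0 fell (4 and 2 both adjusted over the list alone and with the replicate block). The median was −0.03 and the mean 0.03, and camera placed the list upwards without a call (adjusted p = 0.769). Of 22 immediate-early and heat-shock genes, which respond to tissue dissociation, 1 rose and 1 fell, also when adjusted over the list alone, the latter being Atf3, from 2170 ± 182 to 1300 ± 210 CPM (list adjusted p = 0.271, and 0.0119 without Vehicle replicate 1).

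**Figure D3:**
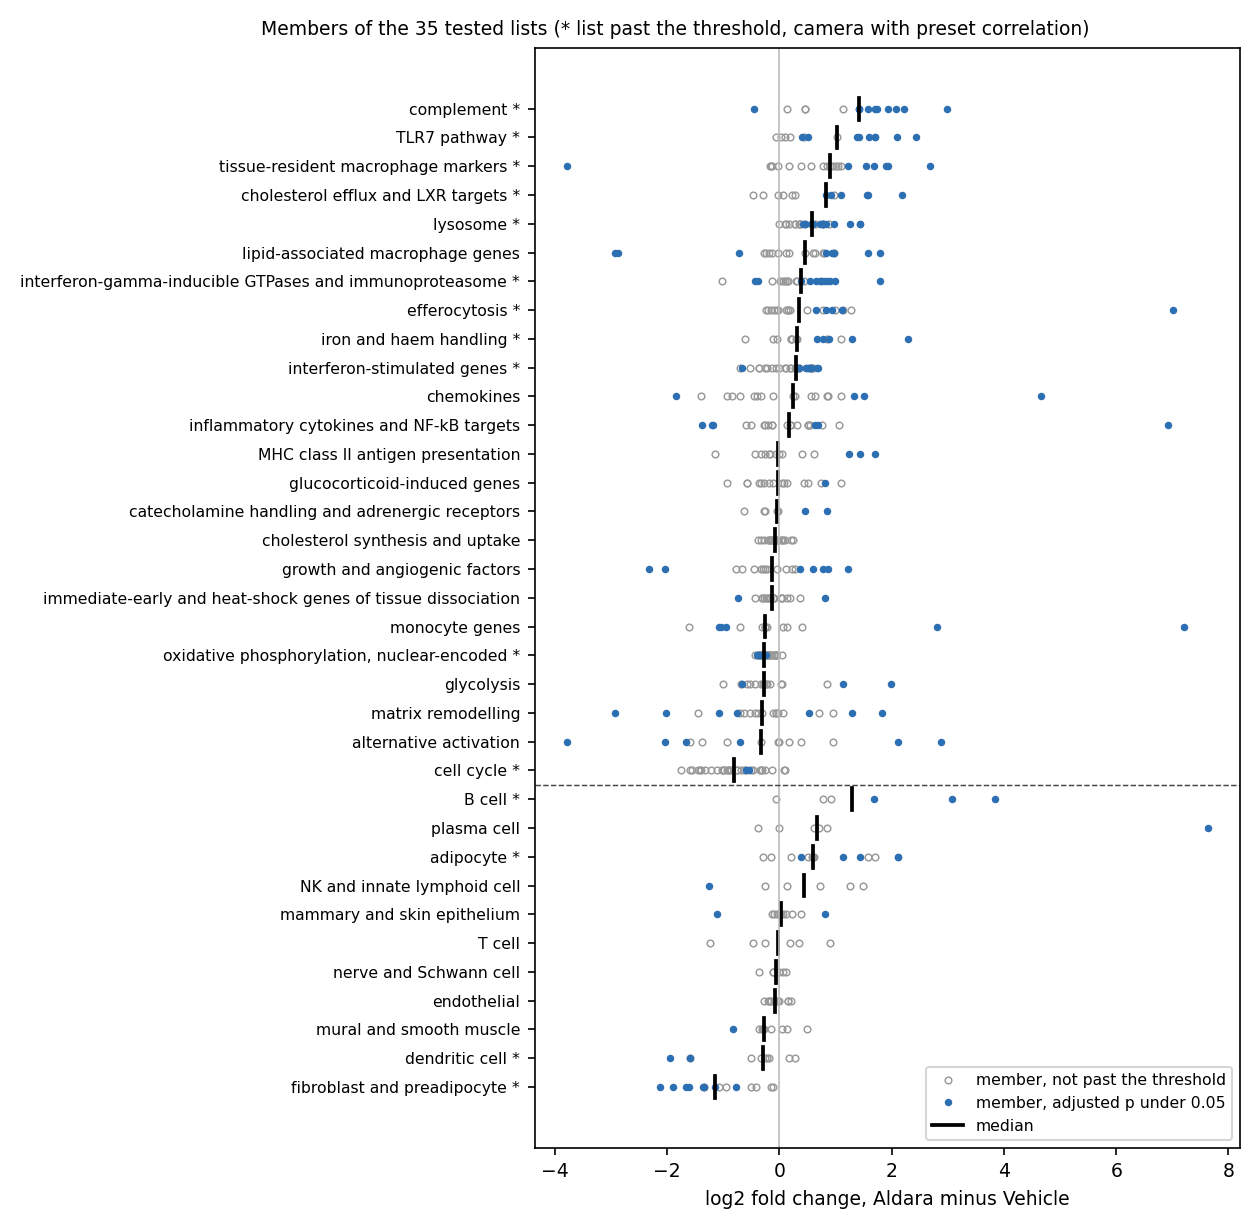
Log2 fold changes (Aldara minus Vehicle) of the members of the 35 tested lists, with program lists above and lists of other cell types below the dashed line. Filled points passed the threshold, black bars are list medians, and asterisks mark the 11 program lists and 4 other lists called by camera with a preset correlation, none of which was called with an estimated one.

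Lists of other cell types moved in both directions. Of 15 fibroblast and preadipocyte genes 0 rose and 8 fell (11 fell adjusted over the list alone), with a median of −1.15. Col3a1, a fibrillar collagen, fell from 123 ± 70.7 to 28.2 ± 9.86 CPM, the proteoglycan Dcn from 37.6 ± 8.71 to 21.9 ± 3.82 CPM, and Lum and Gsn by 1.9 (SE 0.44) and 1.37 (SE 0.33) on the log2 scale. The calls on Lum (without Aldara replicate 2 or 3) and Gsn (without Vehicle replicate 2 or any 1 Aldara library) were lost, with highest adjusted p-values of 0.0728 and 0.0896. For the fibroblast list the camera adjusted p was 6.17e-07 (adjusted p = 0.501 with an estimated correlation). Of 14 adipocyte genes 5 rose and 0 fell (9 and 1 adjusted over the list alone, 5 and 1 with the replicate block). The adipokine Cfd rose from 3.04 ± 0.144 to 13.2 ± 5.98 CPM, Car3, a carbonic anhydrase, from 4.62 ± 0.987 to 12.6 ± 4.33 CPM, the lipid-droplet gene Cidec from 0.664 ± 0.305 to 2.83 ± 1.14 CPM, and Adipoq from 0.569 ± 0.113 to 1.25 ± 0.323 CPM. The call on Adipoq was lost without any library but Aldara replicate 2 (highest adjusted p = 0.0954), and the camera adjusted p of the list was 0.000629 (adjusted p = 0.501 with an estimated correlation).

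Of 6 tested B cell genes 3 rose and 0 fell, also when adjusted over the list alone. Cd79b, a chain of the B cell receptor, rose from 0.408 ± 0.141 to 5.95 ± 2.71 CPM, the inhibitory lectin Cd22 from 0.324 ± 0.103 to 2.76 ± 1.11 CPM and Ighm, the mu heavy chain, from 34.3 ± 8.49 to 111 ± 42.8 CPM. Ighd measured 0.831 ± 0.201 and 1.58 ± 0.768 CPM (adjusted p = 0.179, and 0.0292 without Aldara replicate 1). Cd79a, the partner chain of Cd79b, stayed under the expression filter at 0.113 ± 0.0942 and 0.207 ± 0.12 CPM. The list median was 1.3 and the camera adjusted p 0.000767 (adjusted p = 0.46 with an estimated correlation). Of 10 dendritic cell genes 0 rose and 2 fell, also when adjusted over the list alone. These were the lectin Cd209a (6.54 ± 1.21 to 1.7 ± 0.534 CPM) and Siglech, of plasmacytoid dendritic cells (3.03 ± 1.58 to 1.01 ± 0.218 CPM). Ccr7 measured 0.721 ± 0.274 and 0.229 ± 0.236 CPM (adjusted p = 0.101, and 0.0288 without Aldara replicate 3) and Dpp4 4.13 ± 0.922 and 2.87 ± 0.606 CPM. The list median was −0.3 and the camera adjusted p 0.0126 (adjusted p = 0.46 with an estimated correlation).

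None of the 12 endothelial genes passed edgeR, DESeq2 or voom, and 0 reached an unadjusted p under 0.05. Vwf and Pecam1 measured 274 ± 47.9 and 116 ± 18.7 CPM in Vehicle and 226 ± 49.7 and 129 ± 29.3 CPM in Aldara (list adjusted p = 0.55). Of 10 mural genes 0 rose and 1, Rgs5, fell from 56 ± 11.1 to 31.7 ± 6.08 CPM (2 fell with the replicate block). The list's adjusted p of 0.163 passed the threshold without Vehicle replicate 3 or Aldara replicate 1 (lowest 0.0272). Among 6 T cell genes edgeR and voom called 0 and DESeq2 called 2, with 2 at an unadjusted p under 0.05 (2 fell adjusted over the list alone and 1 with the replicate block, list adjusted p = 0.567). Among 6 nerve genes 0 passed any of the 3 tools or an unadjusted p under 0.05 (list adjusted p = 0.756). In the plasma cell list 1 of 6 rose (2 rose and 1 fell both adjusted over the list alone and with the replicate block). Its adjusted p of 0.0672 passed the threshold without Vehicle replicate 1 or without Aldara replicate 1 or 2 (lowest 0.0253), and under upper-quartile factors (0.0388). In the list of NK and innate lymphoid cells 1 of 6 fell (3 rose and 1 fell adjusted over the list alone, 2 and 0 with the replicate block, list adjusted p = 0.298). Camera called that list upwards with no low-count filter (adjusted p = 0.00011), and fry, which does not compare a list with other genes, called it upwards under the expression filter (0.0294). Without Aldara replicate 1 camera called 7 lists of other cells, against 4 with all libraries. Lists with fewer than 5 tested members were not tested as sets with all libraries and the expression filter. In the neutrophil list 3 of 4 rose, including Csf3r, the granulocyte growth factor receptor (8.73 ± 2.75 to 37.6 ± 16.9 CPM), and Trem1 (0.176 ± 0.0761 to 0.59 ± 0.025 CPM, a call lost without Vehicle replicate 4 at an adjusted p of 0.0512). Where at least 5 of its members were tested, camera called the neutrophil list upwards, in 7 of the 8 fits without 1 library (adjusted p = 6.87e-06 to 8.47e-05) and with no low-count filter (4.15e-09), fits in which no estimated correlation was run. S100a8 and S100a9, calgranulins of neutrophils, measured 0.507 ± 0.0897 and 0.429 ± 0.363 CPM in Aldara. In the eosinophil list 1 of 2 fell (2 both adjusted over the list alone and with the replicate block), in the mast cell and basophil list 1 of 3 rose, and in the erythroid list 1 of 3 fell. With no low-count filter camera called the erythroid list downwards (adjusted p = 0.00908). Such unfiltered calls on the NK, neutrophil and erythroid lists rest in part on members under the expression filter, which hold few counts.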

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

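The tests of the first 3 patterns below were chosen after the results were seen, except that of the oestrogen list, and the counts over other splits of the libraries were planned. For the library totals and 137 genes named in the text, each group of 4 was checked for a library far from the other 3. In 15 of the 276 checks the gap to the nearest library, as a share of the group's range, exceeded the 95% critical value of Dixon's test, where chance gives about 1 in 20.

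The median epithelial gene lay above the median macrophage reference gene in every library although the preparations had passed a gate of more than 90% F4/80 and CD64 positive cells. If other cells had given under 10% of the RNA, macrophages could gain at most 1.11-fold through their share. The mean level of the 23 macrophage reference genes differed by 2.59-fold between the highest and lowest Aldara library and by 1.9-fold within Vehicle. This range argues against so small an admixture unless all these genes rose together within the cells. In each group 23 of 23 genes were higher in the same library. These libraries were picked by the mean of the same genes, so that count is no separate support. A few contaminated libraries were argued against by the epithelial list, whose genes differed by a median of 1.61-fold between the highest and lowest library of each gene. What stays open, as hypotheses, is epithelium of the mammary gland that lies in this fat pad, RNA released on lysis, or libraries that do not correspond to the gated cells, and none of these was tested.

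Macrophage genes were higher in Aldara, and the mean of the reference genes lay 1.62 higher on the log2 scale. A larger share of macrophage RNA as the whole cause requires 1 common factor. Yet 10 of 42 macrophage genes, 2 higher and 8 lower, differed between the groups after scaling to the reference (edgeR, adjusted over these genes). That count is exactly the bound of 10 set for this test. The SEs lay near 0.43. They rest on dispersions estimated over all genes after this scaling, so they do not measure the spread of the macrophage genes alone. Relative to the reference Adgre1 (1.81, SE 0.45) and Itgam (1.24, SE 0.43) were the 2 higher genes. Mgl2 (−5.46, SE 0.51) and Lyve1 (−1.87, SE 0.44) were among the lower ones. The reference itself holds Adgre1 and Itgam, and genes that other cells also express need not follow 1 common factor. The test was not restricted to genes that macrophages alone express, so it cannot decide whether a share was the whole cause. It shows only that these 42 genes did not all change by 1 factor. Neutrophils as the source were argued against by S100a8 and S100a9, which reached at most 0.823 CPM in an Aldara library, where Fpr1 averaged 19.8 and Itgal 160 CPM. Camera nevertheless called the neutrophil list upwards with no low-count filter (adjusted p = 4.15e-09). That call rests in part on members under the expression filter, which hold few counts. A greater share of macrophages with a changed state, or other macrophages entering the tissue, may account for the pattern and was not tested.

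Greb1, Pgr and Areg, which oestrogen or its pathway induces in the mammary epithelium, were lower in Aldara. Fewer hormone-sensing luminal cells as the whole cause were argued against by 6 other markers of these cells, with a median log2 fold change of −0.34, against −1.88 for Pgr (SE 0.36). These markers lay downwards as a set without passing the threshold (camera p = 0.0645 with the preset correlation, and p = 0.209 with an estimated one), and Esr1 was at 0.06 (SE 0.11), Foxa1 at −0.42 (SE 0.18) and Prlr at −0.35 (SE 0.13; adjusted p = 0.1, and 0.0394 with the replicate block). A lower oestrogen response remains a candidate explanation, since 22 tested members of an oestrogen-response list whose values had not been seen were lower as a set (camera p = 0.0464 with the preset correlation, and p = 0.187 with an estimated one), but by a median of −0.22, with 4 fallen and 3 risen. Whether the groups differed in oestrous stage is not in the labels and was not tested.

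The real split gave 1171 rising and 647 falling genes. Each of the other splits of the 8 libraries into 4 and 4, of 35 in all, gave at most 1 of each. This speaks against chance only where the libraries are taken as unpaired. The main fit and these splits took them so, whereas the replicate numbers may pair them. The 8 splits that part all 4 same-numbered pairs are too few for a share under 0.05, so they cannot exclude chance. The highest other among them gave 0 rising and 0 falling genes. The remaining splits keep at least 2 pairs together. For the lists chance cannot be excluded under either reading. The real split called 11 program lists and 4 lists of other cells, whereas 12 splits gave at least 11 called program lists, with up to 19 in another split, and 11 splits gave at least 4 called lists of other cells, with up to 5. Among the 8 splits that part all pairs, the highest other gave 14 program lists and 4 lists of other cells.

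In Vehicle, replicate 1 was the highest for Aoc1 (221 CPM, next 32.8; gap 0.861 of the range), Chst8 (34.2, next 5.25; 0.904) and Col3a1 (229, next 96.6; 0.887), and the lowest for Unc93b1 (143, next 176; 0.854). Vehicle replicate 2 was the highest for Foxa1 (613 CPM, next 376, ratio 0.946). Vehicle replicate 3 was the lowest for Itgal (2.46 CPM, next 4.07, ratio 0.889) and the highest for Blvrb (42.6, next 38.2, ratio 0.858) and Siglech (5.39, next 2.33, ratio 0.954). Vehicle replicate 4 was the highest for Sbp (15.9 CPM, next 5.2, ratio 0.865). In Aldara, replicate 1 was the highest for Tmprss11a (0.0427 CPM, 1 count, the others at 0, ratio 1), the lowest for Cd209a (0.897, next 1.92, ratio 0.91) and the highest for Aqp5 (213, next 166, ratio 0.84). Aldara replicate 2 was the lowest for Atp5b (700 CPM, next 756, ratio 0.919). Aldara replicate 4 was the lowest for Dpp4 (1.97 CPM, next 3.09, ratio 0.877) and the highest for Areg (311, next 137, ratio 0.848).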

How the results depend on the processing

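All alternatives in this part were planned but 1, chosen after seeing the data. Scaling every library to the 23 macrophage reference genes gave 61 higher and 15258 lower genes, which follows from its construction, since it shifts the median of all genes to −1.53, and it was not used further. No gene named in the text and called in either fit changed sign under the settings fixed beforehand. Counts of rising genes stayed within 1.5 times of 1171 under both other scalings, both other filters, protein-coding genes alone, the replicate block, robust=FALSE, DESeq2 and voom (945 to 1546). Falling genes, 647 as reported, numbered 990 under upper-quartile factors, 1030 with the replicate block and 1154 with DESeq2, and 661 to 757 under the others. The cause was not tested. A minimum absolute log2 fold change of 1 left 511 rising and 227 falling genes by its construction. Leaving out 1 library gave 629 to 1405 rising and 323 to 664 falling genes, with fewer samples in each fit. DESeq2 shared 1815 and voom 1633 of the 1818 calls, with 0 of opposite sign. Called program lists numbered 10 to 12 without 1 library, 12 with no low-count filter and 11 under the other filters, scalings and the block. Called lists of other cells numbered 4 to 7 without 1 library, 7 with no low-count filter and 3 to 5 otherwise. Fry called 8 program lists and 5 others, without the interferon-stimulated (adjusted p = 0.226), resident macrophage (0.269), cell cycle (0.285) and fibroblast (0.0543) lists but with the plasma cell list (0.0209) and that of NK and innate lymphoid cells (0.0294). With the replicate block the fry adjusted p was 0.027 for the fibroblast, 0.0502 for the adipocyte and 0.166 for the plasma cell list. With an estimated correlation camera called 0 program lists and 0 others, with 1 and 2 at an unadjusted p under 0.05, where members of a list vary together between libraries (estimated correlations of 0.686 for the lysosome and 0.758 for the cell cycle list). Of the 117 named genes past the threshold, 93 kept their call without any 1 library and 24 lost it at least once. Without a low-count filter 21 of them lost the call, with more genes tested. Beyond the blocked values already given, the replicate block changed no other call on a named gene or, by camera or fry, on a list. The call on Ms4a4c was also lost with a filter of 1 CPM, with protein-coding genes alone and with robust=FALSE. Voom ended the calls on Aoc1, Greb1, Chst8 and Fam83e, and added Cd68 and Ccr7. DESeq2 added Cd68, Csf1r, Birc5, Nusap1 and Prlr, robust=FALSE and protein-coding genes alone each added Cd68 and Csf1r, and the filter of 1 CPM added Csf1r. Other scalings shifted the median log2 fold change of all genes to −0.01 and −0.05, from 0.01. Depth limits the ratio of Tmprss11a, where 1 count over the Aldara libraries leaves an interval of 77.4 to 17100.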

Other observations

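The genes in this part and the 14 families looked at were chosen after their values were seen. Many genes of myeloid receptor families rose, though not every member passed the test. Of 10 tested Cd300 genes, which encode activating and inhibitory lipid-binding receptors, 8 rose and 0 fell, including Cd300a by 2.01 and Cd300ld by 2.03 on the log2 scale. All 4 tested signal regulatory protein genes rose, among them Sirpa, the receptor of CD47, by 1.73. Of 7 genes of the C-type lectin 4 family 5 rose and 0 fell, including Clec4a1 by 2.88 and Clec4a2 by 3.24. Among 4 Fc gamma receptors Fcgr4 rose by 3.64 and Fcgr3 by 1.34, with 0 fallen and Fcgr1 not called (adjusted p = 0.436), and the call on Fcgr3 was lost without Vehicle replicate 1, 2 or 4 or Aldara replicate 3 or 4 (highest edgeR adjusted p = 0.114). Of 11 Toll-like receptors 7 rose (6 under the other 2 scalings) and 0 fell, led by Tlr1 at 2.72. Both Fc receptor-like genes tested, 2 of 3 Slam genes and 7 of 29 integrin genes rose, with 0 fallen (1 integrin gene under upper-quartile factors). Members of other families went both ways, with 3 risen and 1 fallen of 9 membrane-spanning 4A genes, where Ms4a4c fell by 0.96, and 3 risen and 1 fallen of 5 Siglec genes, where Cd22 rose by 3.08 and Siglech fell by 1.6. The call on Ms4a4c was lost without any library but Aldara replicate 3 (highest edgeR adjusted p = 0.13). None of these family medians changed sign under the other 2 scalings, and no family was tested for enrichment. Members of the Cd300, Sirpb and Clec4 families are close paralogs, so the division of reads between them is uncertain. The families lay beside the macrophage reference genes, whose mean lay 1.62 higher on the same scale. Relative to that reference 10 of 42 macrophage genes differed between the groups, 2 higher and 8 lower.

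Several genes of secreted proteins and transporters fell. Gpx3, a secreted glutathione peroxidase, fell from 5210 ± 2880 to 523 ± 301 CPM (log2 fold change −3.32, SE 0.52, adjusted p = 0.00638). Slc5a5, the sodium-iodide symporter, fell by 2.84 (SE 0.39, adjusted p = 0.00417), Aqp5, a water channel, by 2.11 (SE 0.36, adjusted p = 0.00806) and Olfm4, an olfactomedin, by 3.52 (SE 0.57, adjusted p = 0.00695). Of 21 keratin genes 1 rose and 2 fell (0 and 3 under upper-quartile factors), and of 13 claudins 0 rose and 1 fell. Of 7 aquaporins and of 7 genes of solute carrier family 5, 0 rose and 2 fell in each. Of 26 tested genes of the mitochondrial genome 0 rose and 9 fell, including mt-Nd5 by 0.63 (SE 0.15) and mt-Cytb by 0.7 (SE 0.18). These calls were lost without Vehicle replicate 1 or 4 or Aldara replicate 3, and that on mt-Cytb also without Vehicle replicate 3 or Aldara replicate 2 (highest edgeR adjusted p = 0.0669 for mt-Nd5 and 0.0894 for mt-Cytb).

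The row of the table with the hand-written note naming Ccr2 holds the counts of Armh3, between 381 and 707 per library. The row with the identifier of Ccr2 holds 253 to 998 counts, so a reading of the noted row as Ccr2 would use another gene.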
